A study of Mus musculus with 4 samples.

How the data were processed

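Single-cell RNA sequencing was run on lineage-labelled alveolar type II (AT2) cells, the surfactant-producing cells of the lung that also renew the alveolar epithelium, from 4 groups of mice. Per the labels' protocols, control mice carried Sftpc-CreER, 1 floxed and 1 normal Cdc42 allele and the Rosa26-mTmG reporter, and Cdc42 AT2 null mice carried 1 floxed and 1 null allele. Each mouse received 4 doses of tamoxifen, which turns on Cre in cells that express Sftpc, and Cre then deletes the floxed Cdc42 sequence and switches the reporter to GFP. Per the labels' protocols, lungs were digested with neutral protease and DNase, dead cells were marked with DAPI, GFP+ cells were sorted, and libraries were made with the 10x Genomics 3′ single-cell protocol. Each group is 1 library, so there are 4 libraries, and how many mice each library pooled is not given in the sources used here.

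The deposited table holds raw counts of unique molecular identifiers (UMIs) per gene and cell, not normalized, as its values also show: they are whole numbers whose totals differ between cells. Cell Ranger 2.1.0, Seurat 2.3.4 and the mouse build mm10 are named in the submitters' processing notes, without a role or order. The annotation release, the chemistry version and the treatment of doublets are not given in the sources used here. The table has 17117 genes and 10077 cells, each gene was detected in at least 3 cells, and the lowest UMI count of a cell was 691 in control sham, 1171 in control PNX, 1379 in null sham and 2669 in null PNX. This minimum differed between libraries and was set upstream, so shares of shallow cell types can depend on it. The ending of each cell barcode gave its library, as the labels state, and 0 cells were left without a library.

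Cells with at least 500 detected genes and at most 20% mitochondrial UMIs were kept, which left 9827. Doublets were scored per library with Scrublet in scanpy 1.11.5, at an expected rate of 5%. It called 15 cells, 0.153% of those kept, which is too few for a caller that has worked, so doublets remain among the cells. The 9812 cells left were log-normalised to 10000 UMIs, reduced to 2000 variable genes and 30 principal components, joined to 15 neighbours and clustered with the Leiden method (leidenalg 0.10.2) at resolution 0.8. Each of the 25 clusters was named from 18 marker lists. A marker counted when its level was at least 2 times the median over clusters and it was seen in at least 20% of the cluster's cells with 10 or more UMIs. A name needed 4 markers, no tie with another class and no other class with more of the 10 leading genes. The markers were fixed in advance and these thresholds were set after the data had been seen.

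Alveolar epithelial cells were the 8 clusters led by AT2, AT1, transitional or proliferating markers without a tie, 8216 cells in all, and counts were summed over them per library and given as CPM, the usual scaling by the total of the UMIs summed. The 17 other clusters, 1596 cells, were left out of these sums. Among them were 4 without a name, led by Lef1 and Ctla4, by Treml4 and Cd300e, by Mcpt8 and Cpa3, and by Siglech. The cluster led by Treml4 and Cd300e had as many transitional as macrophage markers. Leaving these 4 out was decided after the data were seen. Their shares of the clustered cells are, for control sham, control PNX, null sham and null PNX, 4.36%, 2.09%, 5.01% and 1.57% for the first, 1.75%, 1.05%, 2.06% and 2.18% for the second, 0.436%, 0.455%, 0.584% and 0.174% for the third, and 0.194%, 0.0455%, 0.491% and 0.566% for the last. The lymphocytes used as a background were the T/NK-like and B-like cells. UMIs of alveolar genes in them can come from RNA that droplets take up or from doublets.

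Each comparison is a ratio of CPM with an exact 95% interval from the binomial distribution of the counts of both libraries, and each level has an exact Poisson interval. These intervals cover counting error only. With 1 library per group there is no test and no p-value, and no difference has a replicate check. An added count of 0.5 was used for log2 ratios only. A ratio against a library with 0 counts was computed against 3 counts and is a lower bound.

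Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives except those said to be added later. The 22 lists reported cover AT2 identity and surfactant, AT1 identity, the transitional epithelial state, cell cycle, TGF-β signalling and targets, YAP/TAZ targets, p53 targets and senescence, the unfolded protein response, interferon response, MHC class II, inflammatory and acute-phase secretion, fatty acid synthesis, cholesterol synthesis, immediate-early and heat-shock genes, glycolysis and hypoxia, oxidative phosphorylation, extracellular matrix with integrins and mesenchymal genes, Wnt pathway, FGF and ERK feedback, BMP and Id genes, Notch pathway and ribosomal proteins. Members with a mean of at least 10 CPM over the 4 libraries were measured. The median log2 ratio of all 7054 genes at that level was above 0 in each comparison, so list medians are given relative to it, and a member counts as higher or lower when its ratio relative to it is 1.5 or more, or the inverse of 1.5 or less. Ratios of single genes are given as measured. Each list median has its percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries and is not a test. Intervals of medians over genes, given in the closing section, are binomial intervals from the ordered values.

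Named genes were chosen by a fixed rule. Among genes with at least 20 CPM in the higher library, leaving out mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes and provisional gene models, the 12 highest and 12 lowest ratios were named, ranked by the end of the interval nearest 1. Cdc42, Sftpc, Ager, Hopx, Krt8, Mki67, Tgfb1, Ctgf and Cyr61 were named in any case, and from each list the 2 measured members with the most UMIs and the 2 with the largest ratios. A further list and 3 genes that these rules cover are not reported here. Shares of cells with a UMI were computed after thinning each alveolar cell to 2500 UMIs, the highest multiple of 500 that kept 90% of cells in every library. The genes whose shares are given beyond the 9 named in any case were chosen after their values were seen.

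The ratio, naming and list steps were tested on simulated counts for control PNX over control sham, drawn with counting error only, with 200 of 16748 genes changed. The interval held the true ratio for 95.6% of 6744 measured genes. It is exact for counts drawn this way, so this value says nothing of counts that gather in single cells. The interval excluded 1 on the right side for 100% of the measured genes changed 2-fold, 0.5-fold, 4-fold and 0.25-fold, and 24 of 24 named genes were changed ones. A list of 20 genes changed 4-fold had a median log2 ratio of 2.04 at percentile 100, and one of 20 unchanged genes 0.03 at percentile 86.3. The changes were large for counts with counting error only, so their recovery was nearly certain. It also says nothing of counts that gather in single cells or of differences between animals.

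The alternatives summed all cells or AT2-like cells only, used median-of-ratios or TMM scaling, averaged CPM over cells, thinned cells, changed the CPM filter or the added count, used at least 1000 genes and at most 10% mitochondrial UMIs, kept called doublets, and clustered at resolution 0.4 or 1.5. Those added after the data were seen left out the highest doublet scores, clustered without the 612 marker and listed genes, left out the cell with most UMIs of each gene, or applied 1 minimum of 2669 UMIs to every library. Coordinates and gene types are from GENCODE release M21 on GRCm38, the assembly also called mm10, which held 16513 of the table's symbols (96.5%). Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.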

Results

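The series asked how alveolar regeneration after pneumonectomy (PNX, surgical removal of part of the lung, which makes the remaining lung grow) depends on Cdc42, a small GTPase that organises actin and cell shape. GFP+ lineage-labelled AT2 cells were sequenced from 4 groups of 1 library each: control without PNX (control sham), control on day 21 after PNX (control PNX), Cdc42 AT2 null without PNX (null sham) and Cdc42 AT2 null on day 21 after PNX (null PNX). The labels give postnatal day 80 for every library, and it is not clear whether this is the age at surgery or at collection. A difference in age between PNX and sham mice is thus not ruled out. Because each group was 1 library, every difference below is a difference between libraries that no replicate checked, and every interval covers counting error only.

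Control sham had 2111 cells and 9868802 UMIs, control PNX 2252 cells and 11233796, null sham 3344 cells and 17828596, and null PNX 2370 cells and 24897537. Null PNX cells were the deepest, with a median of 9705.5 UMIs per cell against 4503 in control sham, 4713 in control PNX and 4844.5 in null sham. The sums over alveolar epithelial cells used below rested on 1686 control sham, 1969 control PNX, 2642 null sham and 1919 null PNX cells, with 8335388, 10110132, 14858205 and 21915626 UMIs. A floor of 3 counts lay at 0.360 CPM in control sham, 0.297 in control PNX, 0.202 in null sham and 0.137 in null PNX.

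Cdc42 itself, the floxed gene, had 185 CPM in control sham, 226 in control PNX, 264 in null sham and 413 in null PNX. Its ratio was 1.43 (95% interval 1.35–1.52) in null sham over control sham and 1.83 (1.75–1.92) in null PNX over control PNX, so Cdc42 tags were more frequent in the null libraries. The library protocol counts 3′ tags and the labels do not give the floxed exon, so these values do not tell whether the gene was deleted. Lymphocytes, which do not express Sftpc-CreER, had 591, 488, 547 and 789 CPM in the same order.

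Most sorted cells carried AT2 genes, and the 4 largest AT2-like clusters each came mostly from 1 library, with 1443 control sham, 1362 control PNX, 2203 null sham and 1164 null PNX cells. Clustered without listed genes, 3 AT2-like clusters mixed the control libraries, with 977, 420 and 269 control sham and 793, 590 and 438 control PNX cells. The last of them also held 204 null sham cells. A transitional-like cluster, marked by genes of the state between AT2 and AT1 cells, held 541 null PNX cells, or 23.6% of that library's clustered cells (exact 95% interval 21.8–25.4), against 0, 2 and 3 cells in control sham, control PNX and null sham. A proliferating-like cluster held 123 null PNX cells (5.36%, 4.47–6.36) against 4, 11 and 0. Both depended on the clustering, and the transitional-like share was 46.8% at resolution 1.5 and 53.3% with the stricter cell filter. With the 612 listed and marker genes left out of the clustering, 217 null PNX cells (9.46%, 8.29–10.7) were transitional-like, with 0 in each other library. The exact 95% interval of these 0 counts reaches 0.179% in control sham, 0.168% in control PNX and 0.113% in null sham. No proliferating-like cluster was found with these genes left out, and an unnamed cluster led by Cdc20, Cdca3 and Sprr1a held 528 null PNX cells. Cells of null PNX were deeper, came from the same GFP+ sort and had the highest minimum of UMIs per cell, and a cluster mostly of 1 library may be that library rather than a cell state.

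There was no AT1-like cluster. An unnamed alveolar cluster led by Kcnk2, Col4a4, Npnt and Hopx made up 20.009% of control PNX cells, 2.28% of control sham cells, 0.430% of null sham cells and 0.305% of null PNX cells. These shares depended on the clustering. Clustered without listed genes, an AT2-like cluster also had Kcnk2, Col4a4 and Npnt among its 10 leading genes. It held 269 control sham, 438 control PNX, 204 null sham and 3 null PNX cells. Summed Hopx was not higher in control PNX, at 35.2 CPM against 47.3 in control sham. Another unnamed alveolar cluster, led by Gsta1, Fxyd2 and Pf4, made up 11.026% of null sham cells against 0.0970% of control sham, 0.364% of control PNX and 1.002% of null PNX cells. It had 2609.6 CPM of Krt8 and 44.4 of Cldn4, against 5081.2 and 1245.1 in the transitional-like cluster. The AT2-like cluster mostly of null sham cells had 540 and 2.28. Null sham thus held a cluster with high Krt8 although few of its cells were named transitional-like. Cells outside the alveolar clusters were 18.2% of clustered cells in control sham, 10.5% in control PNX, 18.9% in null sham and 16.4% in null PNX, although the sort was for GFP.

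The genes named in advance cover AT2 and AT1 identity, proliferation, the keratin of the transitional state and readouts of TGF-β and YAP. On mm10, with M21 coordinates, these protein-coding genes lie at chromosome 4 137319696–137357720 (Cdc42), chromosome 14 70520949–70524081 (Sftpc), chromosome 17 34597862–34600936 (Ager), chromosome 5 77086988–77115121 (Hopx), chromosome 15 101996698–102004482 (Krt8), chromosome 7 135689784–135716361 (Mki67) and 25687002–25705077 (Tgfb1), chromosome 10 24595442–24598683 (Ctgf) and chromosome 3 145646976–145649981 (Cyr61). Krt8, a keratin of stressed and transitional alveolar cells, was lowest in control sham (137 CPM), higher in control PNX (202) and null sham (955) and highest in null PNX (2610.3). Cyr61, a YAP target, had 204 CPM in null PNX against 11.5, 9.20 and 7.20 in control sham, control PNX and null sham. Sftpc, the AT2 surfactant gene, had 128497 and 122091 CPM in the control sham and control PNX libraries and 68544 and 61014 in the null sham and null PNX libraries. Ager, an AT1 gene that AT2 cells express at a low level, had 1339, 1472, 516 and 1143 CPM in the order control sham, control PNX, null sham and null PNX, and Hopx 47.3, 35.2, 16.2 and 31.0. Tgfb1 had 22.2, 20.1, 36.2 and 52.5 CPM in that order, and Mki67, made by dividing cells, 2.76, 4.06, 0.740 and 10.5. Ctgf, induced by TGF-β and YAP, was scarce outside null PNX, with 1.44, 1.58, 1.01 and 16.6 CPM in that order. Mki67 and Ctgf lay below the mean of 10 CPM over the libraries that a gene needed to be counted in its list, so they are given apart from the list counts.

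**Figure D1:**
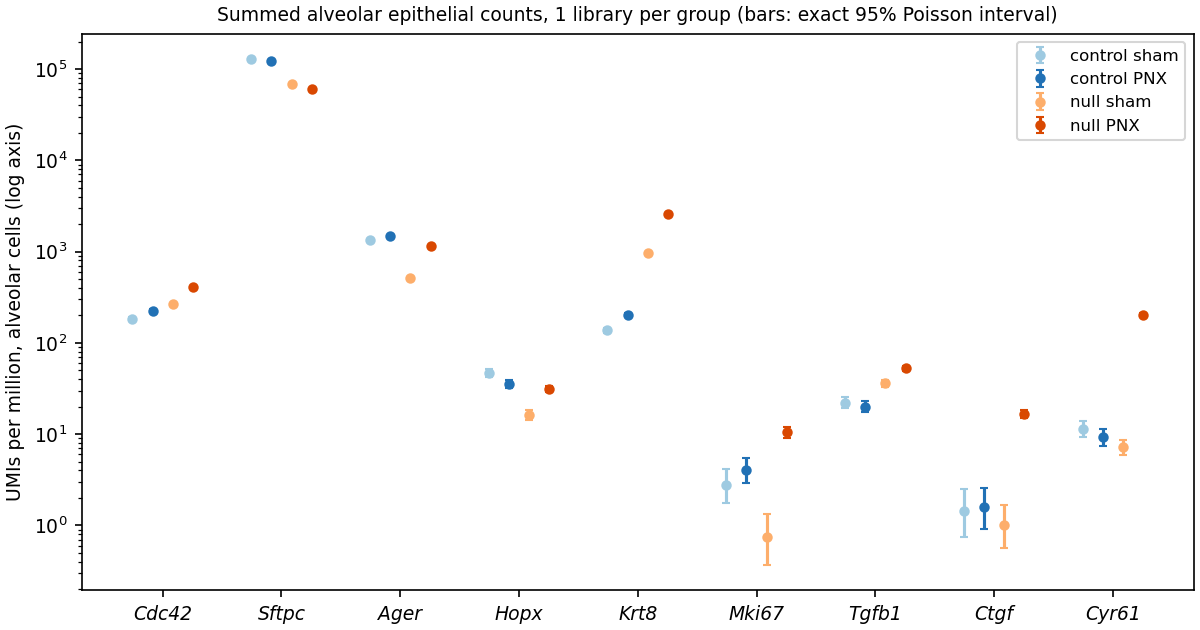
Level in CPM (log axis) of the 9 genes named in advance, summed over alveolar epithelial cells of the 4 libraries; bars are exact 95% Poisson intervals for counting error. Krt8 reached 2610.3 CPM in null PNX against 137 in control sham.

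Control PNX was compared with control sham to describe AT2 cells on day 21 of normal regrowth. Some unfolded protein response and p53-pathway genes were higher in control PNX, some interferon and early-response genes were lower, and nearly all surfactant genes were similar. Null sham over the same control sham library, without PNX, had similar medians for several lists. They were 0.47 for the unfolded protein response, -0.53 for interferon, -0.39 for immediate-early and heat-shock and -0.47 for cholesterol genes. The p53 median there was 0.15. A difference of the control sham library is not ruled out as the source. The lower p53 median does not exclude it for that list, since null sham is 1 library of another genotype. In the unfolded protein response list 8 of 17 measured genes were higher and 1 lower in control PNX (median log2 0.49 relative to all genes, percentile 100). Examples are Calr, an ER chaperone, at 1.86 times control sham and Sdf2l1 at 3.33. Among p53 targets and senescence genes 5 of 15 were higher and 2 lower (0.44, percentile 100), with Phlda3 at 3.02, Zmat3 at 2.56 and Bax at 1.98. AT1 identity was slightly higher, with 4 of 17 genes higher and 0 lower (0.28, percentile 100). Krt7 was at 1.77, Cryab at 1.93 and S100a14 at 1.93, while Ager, at 1.10, counted as neither.

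Of 14 extracellular matrix, integrin and mesenchymal genes 4 were higher and 1 lower (0.29, percentile 100). Lama3 and Lamb3, which encode laminin chains, were at 3.87 and 4.66 (3.54–6.23) times control sham, and Sparc was at 2.16. The median of this matrix and integrin list was -0.09 with no filter on CPM, so its direction depends on the filter. In the transitional list 3 of 22 genes were higher and 2 lower (0.29, percentile 100). The abundant members S100a6 at 1.63, Clu at 1.35 and Krt8 at 1.47 (1.37–1.58) counted as neither once the all-gene shift was taken out, and Plaur was lower at 0.481. This list median was 0.04 when only AT2-like clusters were summed. Of 10 cell cycle genes 4 were higher and 0 lower (0.45), with Birc5 at 2.04 and Cdc20 at 1.95. Of the genes named in advance, Mki67 was at 1.47 (0.861–2.57), Ctgf at 1.10, Cyr61 at 0.799 (0.594–1.07), Tgfb1 at 0.905 (0.738–1.11), Hopx at 0.745 and Cdc42 at 1.22.

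Of 13 interferon response genes 6 were lower and 0 higher in control PNX (-0.57, percentile 0), including Ifi27l2a at 0.180, Rtp4 at 0.454 and Ifi27 at 0.667. Immediate-early and heat-shock genes were split, with 11 of 24 lower and 5 higher (-0.54, percentile 0). The lower ones included the early-response transcription factors Nr4a1, by 4.66-fold, Egr1 by 3.36-fold, Atf3 by 2.92-fold and Ier2 by 2.62-fold. The higher ones included the heat-shock genes Hsph1, by 9.66-fold (6.42–15.2), and Hspa1b, by 7.99-fold (5.58–11.8). In cholesterol synthesis 3 of 20 genes were lower and 0 higher (-0.39, percentile 0), which were Insig1 at 0.652, Lss at 0.667 and Fdft1 at 0.693.

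AT2 identity and surfactant genes barely differed, with 1 of 24 lower and 0 higher (-0.15). Sftpc was at 0.9501, Sftpa1 at 0.836, Lyz2 at 0.719 and Cxcl15 at 1.40. Signalling lists were also close between the libraries: 2 of 21 TGF-β genes were higher and 1 lower (0.02), and 2 of 13 YAP/TAZ targets higher and 0 lower (0.21). Among these F3 was at 2.37 and Myof at 1.70. In the BMP and Id list 2 of 9 genes were higher (0.27), Id1 at 1.74 and Id3 at 1.86, with 0 lower. Of 4 Notch genes Hes1 was higher at 1.66 and 0 were lower (0.07), while 0 of 6 Wnt genes (-0.19) and 0 of 8 FGF and ERK feedback genes (-0.06) were higher or lower.

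MHC class II genes had a median of 0.08, with 1 of 7 higher (H2-DMb2, 1.93) and 1 lower (H2-Eb1), while Cd74 was at 1.14 and H2-Aa at 1.25. In the inflammatory list 1 of 14 genes was higher and 4 lower (-0.11), including Il1b at 0.189. Macrophage markers in the same alveolar cells were lower in 3 of 5 cases and higher in 1 (-1.18), so less macrophage RNA is not ruled out. In the fatty acid list 1 of 16 genes was lower and 0 higher (-0.07). In the glycolysis and hypoxia list 2 of 16 were higher and 0 lower (-0.11), with Pgk1 at 2.59. None of the 20 oxidative phosphorylation genes (-0.02) or the 22 ribosomal protein genes (-0.29) was higher or lower.

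The named genes of this comparison included several whose size rested on 1 cell. Camp (at least 289-fold), Ngp (1071-fold, 192–42333), S100a8 (9.78-fold, 8.69–11.035), Chil3 (7.55-fold) and S100a9 (4.65-fold), all genes of the neutrophil lineage or macrophages, were higher in control PNX. The control PNX cell with most UMIs, found for each gene apart, held 96.8%, 95.9%, 93.5%, 94.7% and 92.2% of their UMIs in that order. Without each gene's highest cell Camp had 3.36 CPM in control PNX against 0 in control sham and Ngp 5.24 against 0.120, so both stayed higher. Without each gene's highest cell S100a8 had 23.0 CPM in control PNX against 36.0 in control sham, Chil3 1.58 against 3.96 and S100a9 17.1 against 47.4, the reverse direction. Hist1h2ap, a histone gene of dividing cells, was 5.81-fold higher, with 38.5% of its UMIs in 1 cell. Nr1d1, a clock repressor, was 7.89-fold higher (6.54–9.61), Fam126a 5.35-fold and Fam150a 4.59-fold. The lowest genes were H2-Eb1, an MHC class II chain, with 30.8 CPM against 419 (13.6-fold, 12.1–15.3), Dynlrb2 (9.50-fold), Pttg1 (7.17-fold), Ifi27l2a (5.57-fold), Ccl5 (4.02-fold, with 7241 CPM in control sham lymphocytes against 23.0 in the alveolar cells) and Cst8 (2.87-fold). Scgb1a1, the club cell secretory gene, was 3.26-fold lower, and 16.1% of its control sham UMIs lay in 1 cell. Retnla was 2.87-fold lower only through 1 control sham cell with 63.3% of its UMIs, without which it had 52.2 CPM in control sham and 49.5 in control PNX.

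Null PNX was compared with null sham to describe the same surgery in the null genotype. The transitional genes were higher almost throughout, together with matrix, p53 and cell cycle genes, while most fatty acid genes were lower. Of 22 transitional genes 21 were higher and 0 lower in null PNX (median log2 1.92, percentile 100). Clu, a secreted chaperone, was at 19.1 times null sham (18.5–19.8), Cldn4, a tight-junction claudin, at 30.1 (26.2–34.9), Sprr1a at 51.2 (35.6–76.7), Krt8 at 2.73 (2.68–2.78) and S100a6 at 1.81. Of 14 extracellular matrix, integrin and mesenchymal genes 9 were higher and 1 lower (0.92, percentile 100), with Fn1 at 13.1, Itgb6, the integrin chain that activates latent TGF-β, at 10.9 and Sparc at 3.60. Fn1 had 363 CPM in the other cells of null PNX and 175 in those of null sham. Its alveolar level in null PNX was 54.8 CPM, so RNA of other cells is not ruled out for it.

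Cell-cycle arrest and proliferation genes were both higher in null PNX. Of 15 p53 and senescence genes 10 were higher and 0 lower (0.85, percentile 100), including the inhibitors Cdkn1a at 7.32 and Cdkn2b at 6.70, with Phlda3 at 9.30 and Bax at 2.41. Of 10 cell cycle genes 8 were higher and 0 lower (1.26, from 0.79 to 3.24 over the alternatives), with Birc5 at 71.7, Cdc20 at 21.2, Tubb5 at 2.68 and H2afz at 2.98. Outside the list counts, Mki67 was at 14.2 (7.78–28.8). Of 16 glycolysis and hypoxia genes 8 were higher and 3 lower (0.50). Eno1 was at 5.74, Gapdh at 2.23 and Ldha at 1.83, while Hk2 was at 0.191.

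Of 21 TGF-β genes 10 were higher and 3 lower (0.39), with Fn1, Itgb6 and Thbs1, at 1.98, among the higher, while Tgfb1, at 1.45, counted as neither. The YAP/TAZ list was divided, with 4 of 13 higher and 3 lower (-0.10). Cyr61 was at 28.4 (23.4–34.7), F3 at 5.9995 and Gadd45a at 2.95, while Rbms3 was at 0.360. Ctgf, not counted in the list, was at 16.4 (9.82–29.6). The YAP/TAZ median has no stable direction, since it was 2.32 with only genes of at least 50 CPM. Cdc42 was at 1.56 (1.51–1.62).

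Of 24 AT2 identity genes 12 were lower in null PNX and 1 higher (-0.55), a median that matched random lists also reached (percentile 7.91). Etv5, a transcription factor that maintains AT2 cells, was at 0.331 and Sftpa1 at 0.709, while Chil1 was at 3.02. Sftpc, at 0.890, counted as neither, and its log2 ratio turned from -0.17 to 0.14 when only AT2-like clusters were summed. Fatty acid synthesis had 10 of 16 genes lower and 0 higher (-1.02, percentile 0.02), with the desaturases Scd1 at 0.387, Scd2 at 0.339 and Fads1 at 0.428 and the lipid carrier Fabp5 at 0.270. The cholesterol list had 7 of 20 lower and 1 higher (-0.30), with Srebf2 at 0.380 and Insig1 at 0.599. FGF and ERK feedback genes were lower in 6 of 8 cases and higher in 1 (-0.96, percentile 0.06), with Fgfr2 at 0.401, Spred2 at 0.480 and Dusp6 at 2.95. Of 6 Wnt genes 3 were lower and 1 higher (-0.65), with Axin2 at 0.259 and Sp5 at 2.91. Of 4 Notch genes 2 were lower and 0 higher (-0.58, percentile 6.77), with Notch1 at 0.482, and of 9 BMP and Id genes 2 were lower and 1 higher (-0.33, percentile 14.975), with Id2 at 0.576 and Id1 at 2.38.

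AT1 genes differed in both directions, with 5 of 17 higher and 2 lower (0.32). Ager was at 2.22 (2.16–2.27), Hopx at 1.91, Krt7 at 3.84 and S100a14 at 4.68, but the AT1 collagen Col4a4 was at 0.497. Immune and stress lists were higher in part: MHC class II in 4 of 7 genes with 0 lower (0.75), inflammatory genes in 6 of 14 with 0 lower (0.53), interferon genes in 6 of 13 with 1 lower (0.34) and immediate-early and heat-shock genes in 9 of 24 with 2 lower (0.42). Among them Cd74 was at 2.14, H2-DMa at 2.42, Ptges at 4.34, Lcn2 at 2.49, Isg15 at 4.78, Psmb8 at 2.66 and Hspa1a at 13.5. The interferon median was -0.04 when all cells were summed, so it has no stable direction. Club cell markers in the same alveolar cells were also higher at the median, so club RNA is not ruled out for the inflammatory genes. Scgb1a1, one of these markers, was lower, at 1482 CPM in null PNX against 4841 in null sham.

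The unfolded protein response list was split in null PNX over null sham, with 4 of 17 higher and 4 lower (0.21), Atf3 being at 7.13 and Herpud1 at 0.283. Of 20 oxidative phosphorylation genes 3 were higher and 0 lower (0.05), with Uqcrc1 at 2.48 and Atp5b at 2.296. Of 22 ribosomal protein genes 15 were lower and 0 higher (-0.66), with Rps19 at 0.571, a median that matched random lists also reached (percentile 11.7). The named genes with the highest ratios included Rgs4 (at least 174-fold), Ntm (481-fold, 86.0–19012), Cda (at least 104-fold), Fhl2 (136-fold, 52.8–499), a LIM protein of the actin and YAP response, Sdcbp2 (133-fold), Anxa8 (127-fold), Ccnb2 (83.6-fold), Spp1 (78.1-fold) and AW112010 (42.5-fold). For Spp1, AW112010 and Fhl2 null PNX lymphocytes had 46.7, 821 and 40.9 CPM, against 26.3, 169 and 36.5 in the alveolar cells. RNA of other cells is thus not ruled out for them, though the Fhl2 levels were close and the lymphocytes were only 87 cells. All other cells together had 2319.5 CPM of Spp1 in null PNX and 52.2 in null sham. In null sham, lymphocytes had 1674 CPM of AW112010 and 32.0 of Fhl2, with 3.97 and 0.269 in the alveolar cells. For these genes a high lymphocyte level alone did not go with a high alveolar level. In the other cells of null PNX, Anxa8 had 53.6 CPM and Ccnb2 35.5, also above their alveolar 25.7 and 22.5. Bpifa1, an airway secretory gene, was at least 168-fold higher, but 70.7% of its UMIs lay in 1 cell. The named genes with the lowest ratios included the circadian output factors Dbp (17.0-fold lower) and Tef (11.4-fold), the glucocorticoid-induced factor Klf15 (23.3-fold), Cyp2b10 (23.7-fold), Cbr2 (13.1-fold), Ppp1r1b (11.3-fold), Tex11 (10.3-fold), Vpreb3 (8.54-fold), Hist2h2aa1 (8.52-fold), Bex4 (7.98-fold), Itpr2 (7.29-fold) and Cox6a2 (6.497-fold).

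Null sham was compared with control sham to describe AT2 cells of the null genotype without PNX. Keratins and many transitional genes were higher in null sham, and Sftpc and several interferon genes were lower. Of 22 transitional genes 16 were higher and 3 lower (median log2 1.39, percentile 100, from 0.89 to 2.16 over the alternatives). S100a6 was at 10.3 (9.85–10.8), Krt8 at 6.96 (6.55–7.39), Krt19 at 7.76, Clu at 3.08 and Cldn4, with 0 UMIs in control sham, at 36.8 or more. In the matrix and integrin list 5 of 14 genes were higher and 0 lower (0.46, percentile 100), with Lamb3 at 8.65.

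Of 24 AT2 identity genes 6 were lower and 0 higher (-0.20). Sftpc was at 0.533 (0.532–0.535), Chil1 at 0.416 and Hc, complement C5, at 0.115, while Sftpa1 was at 1.03. AT1 genes were divided, 5 of 17 higher and 3 lower (0.01), with Krt7 at 5.29, S100a14 at 5.63 and Timp3 at 2.95 against Ager at 0.385 (0.374–0.397) and Hopx at 0.343. YAP/TAZ targets were more often lower, 5 of 13 against 2 higher (-0.36, percentile 0.09). Amotl2 was at 0.438, Tead1 at 0.521 and Cyr61 at 0.625, but F3 was at 7.59. Ctgf, not counted in the list, was at 0.701 (0.306–1.64). Of 21 TGF-β genes 5 were higher and 3 lower (0.30), with Thbs1 at 2.89, Bhlhe40 at 2.31, Fn1 at 8.70 (3.23–32.9) and Ltbp3 at 0.441, while Tgfb1, at 1.63, counted as neither.

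Interferon genes were lower in 6 of 13 cases and higher in 0 (-0.53, percentile 0), with Ifi27l2a at 0.176 and Isg15 at 0.458. MHC class II genes were lower in 3 of 7 cases and higher in 0 (-0.58), with H2-DMa at 0.584 and H2-Eb1 at 0.0416. Cholesterol genes were lower in 8 of 20 cases and higher in 0 (-0.47, percentile 0), with Insig1 at 0.485 and Hmgcs1 at 0.585. Immediate-early and heat-shock genes were lower in 11 of 24 cases and higher in 6 (-0.39, percentile 0), with Atf3 at 0.363 among the lower and Hspb1 at 5.34 and Klf2 at 3.76 among the higher. Unfolded protein response genes were higher in 5 of 17 cases and lower in 1 (0.47), with Calr at 1.71 and Sdf2l1 at 1.99 among the higher. Glycolysis and hypoxia genes were higher in 5 of 16 and lower in 0 (0.32), with Ndrg1 at 6.45 and Gapdh at 1.97.

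Of 10 cell cycle genes 2 were lower and 0 higher in null sham (0.01), and the sign of this median turned under other filters. Birc5 was one of the 2, at 0.157 (0.0574–0.374), and H2afz was at 0.954. Mki67, not counted in the list, was at 0.268 (0.118–0.573). Of 15 p53 genes 3 were higher and 3 lower (0.15), with Gdf15 at 3.10 and Cdkn1a at 0.614. Inflammatory genes were 4 higher and 4 lower of 14 (-0.06), with Cxcl2 at 2.35 and Chil1 at 0.416, and fatty acid genes 2 higher and 0 lower of 16 (-0.18), with Acot7 at 2.55 and Agpat2 at 2.08. Of 6 Wnt genes 2 were lower and 0 higher (-0.44), Nkd1 being at 0.657. Of 8 FGF genes 1 was higher and 2 lower (-0.13), with Spry2 at 0.596, and of 9 BMP genes 2 were lower and 0 higher (-0.11), with Bmp4 at 0.551. Of 4 Notch genes 1 was lower and 0 higher (-0.15), and 0 of 20 oxidative phosphorylation genes (-0.02) and 0 of 22 ribosomal protein genes (-0.12) were higher or lower.

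The highest named genes in null sham were Gsta1, a glutathione transferase (93.1-fold, 25.6–772), Myh6 (34.5-fold), Fxyd2 (13.3-fold), Mid1 (9.95-fold), Rasd2 (8.63-fold), Tnfsf9 (8.53-fold) and the tropomyosin Tpm2 (8.10-fold), beside S100a6, Krt19, Lamb3, Krt8 and F3. The lowest were Retnla (25.1-fold, resting in part on the control sham cell described above), H2-Eb1 (24.0-fold), Rasl11a (21.0-fold), Hc (8.72-fold), Pttg1 (8.66-fold), Nnat (6.02-fold), Ifi27l2a (5.68-fold), Dynlrb2 (5.31-fold) and Snhg11 (4.73-fold). Lipid transport genes were also among them, with Lpl 5.28-fold, Apoe 4.23-fold and Apoc1 3.52-fold lower. H2-Eb1, Ifi27l2a, Dynlrb2 and Pttg1 were lower than control sham in both control PNX and null sham.

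Null PNX was compared with control PNX to describe the genotypes on day 21 after surgery. All 22 measured transitional genes were higher in null PNX (median log2 3.31, percentile 100), and 13 of 24 AT2 identity and 11 of 16 fatty acid genes were lower. Clu was at 43.7 times control PNX (41.0–46.6), Krt8 at 12.9 (12.4–13.5), S100a6 at 11.5, Plaur, the urokinase receptor, at 84.2 (40.7–210) and Cldn4, with few control PNX UMIs, at 807.5 (346–2488). Lymphocytes of null PNX had 216 CPM of Krt8. Of 14 matrix, integrin and mesenchymal genes 10 were higher and 0 lower (1.02, percentile 100). Their member Fn1 had 363 CPM in the other cells of null PNX and 38.9 in those of control PNX. Its alveolar level in null PNX was 54.8 CPM, so RNA of other cells is not ruled out for it.

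Of 21 TGF-β genes 10 were higher and 5 lower in null PNX (0.48). Itgb6 was at 11.3, Thbs1 at 4.34, Tgfb1 at 2.62 and Fn1, with few control PNX UMIs, at 554 (99.3–21902). Among 13 YAP/TAZ targets 3 were higher and 7 lower (-0.67, percentile 0.23). The matricellular gene Cyr61 at 22.2 (18.1–27.6) and the clotting initiator F3 at 19.2 were higher, and Rbms3 at 0.273 was lower. Ctgf, not counted in the list, was at 10.5 (6.36–18.5). The YAP/TAZ median turned to 0.09 with no filter on CPM and to 3.97 with only genes of at least 50 CPM, so it gives no direction for the list. Of 10 cell cycle genes 8 were higher and 1 lower (1.16), with Cdc20 at 7.58, Birc5 at 5.51 and H2afz at 2.27. Mki67, not counted there, was at 2.59 (1.85–3.70). Of 15 p53 genes 7 were higher and 0 lower (0.57), with Cdkn2b at 4.94, Phlda3 at 3.39 and Cdkn1a at 3.02.

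AT2 identity was lower in 13 of 24 genes and higher in 1 (-0.75, percentile 0.5), with Sftpc at 0.4998, S100g at 0.234 and Hc at 0.0775. AT1 genes were divided, 6 of 17 higher and 5 lower (-0.09), with Krt7 at 11.5 and S100a14 at 13.7 against Col4a4 at 0.317 and Ager at 0.777. Hopx, at 0.881 (0.774–1.0046), counted as neither. Fatty acid genes were lower in 11 of 16 cases and higher in 1 (-0.97, percentile 0.01), with Scd1 at 0.293, Scd2 at 0.296 and Fabp5 at 0.338. Cholesterol genes were lower in 8 of 20 and higher in 0 (-0.34), with Insig1 at 0.445. Glycolysis and hypoxia genes were higher in 9 of 16 and lower in 2 (1.13, percentile 100), with Ndrg1 at 13.5, Eno1 at 10.1 and Gapdh at 3.83.

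Several genes of the FGF, Wnt, BMP and Notch lists were lower in null PNX. Of 8 FGF and ERK feedback genes 4 were lower and 1 higher (-1.005, percentile 0.1), with Fgfr2 at 0.378, Etv5 at 0.356 and Spry2 at 0.387. Of 6 Wnt genes 4 were lower and 0 higher (-0.91), with Axin2, a direct Wnt target, at 0.305. Of 9 BMP and Id genes 5 were lower and 0 higher (-0.79), with Bmp4 at 0.567, and of 4 Notch genes 3 were lower and 0 higher (-0.91), with Jag1 at 0.549. Inflammatory genes were higher in 8 of 14 cases and lower in 3 (0.79), with Cxcl2 at 9.37, Il1b at 6.62 and Lcn2 at 2.80. Of 5 macrophage markers measured in these alveolar cells 3 were also higher and 2 lower (1.10), so macrophage RNA is not ruled out as a source. Immediate-early and heat-shock genes were higher in 10 of 24 and lower in 3 (0.49), with Klf2 at 17.2 and Atf3 at 7.57. Interferon genes were higher in 5 of 13 and lower in 1 (0.47), with Isg15 at 4.54 and Psmb8 at 2.26. This median was -0.04 when only genes of at least 50 CPM were measured.

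Of 7 MHC class II genes 0 were higher and 1 lower in null PNX over control PNX (0.08), the lower one being H2-Eb1 at 0.765. Of 17 unfolded protein response genes 4 were higher and 3 lower (-0.03), with Asns at 5.32. Of 20 oxidative phosphorylation genes 5 were higher and 1 lower (0.05), with Atp5b at 3.45, and of 22 ribosomal protein genes 7 were lower and 0 higher (-0.45, percentile 34.9), with Rplp1 at 0.482. Several of the highest named genes had only a few UMIs in control PNX, so their intervals are wide: Kng2 (768-fold, 138–30356), Lrrc26 (364-fold), Rgs4 (355-fold), Bpifa1 (344-fold), Gkn2 (322-fold), Spp1 (266-fold), Anxa8 (260-fold) and Fhl2 (185-fold). AW112010 was 77.5-fold higher (51.1–124), and it, Spp1 and Fhl2 have the lymphocyte levels given above. The lowest included Klf15 (36.3-fold), Dgkg (16.3-fold), Lpl (14.6-fold), Bex1 (14.4-fold), Cyp2b10 (14.1-fold), Hc (12.9-fold), Ppp1r1b (12.031-fold), Fam178b (10.6-fold) and Scgb1c1 (9.72-fold). Ngp (2816-fold), Camp (2280.4-fold) and S100a8 (11.4-fold) were also lower in null PNX, each with most of its control PNX UMIs in 1 cell. Without its highest cell Ngp had 5.24 CPM and Camp 3.36 CPM in control PNX, still above the 0.0456 CPM of each in null PNX. Without each gene's highest cell the log2 ratio of S100a8 was 0.40 in place of -3.51, the reverse direction.

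**Figure D2:**
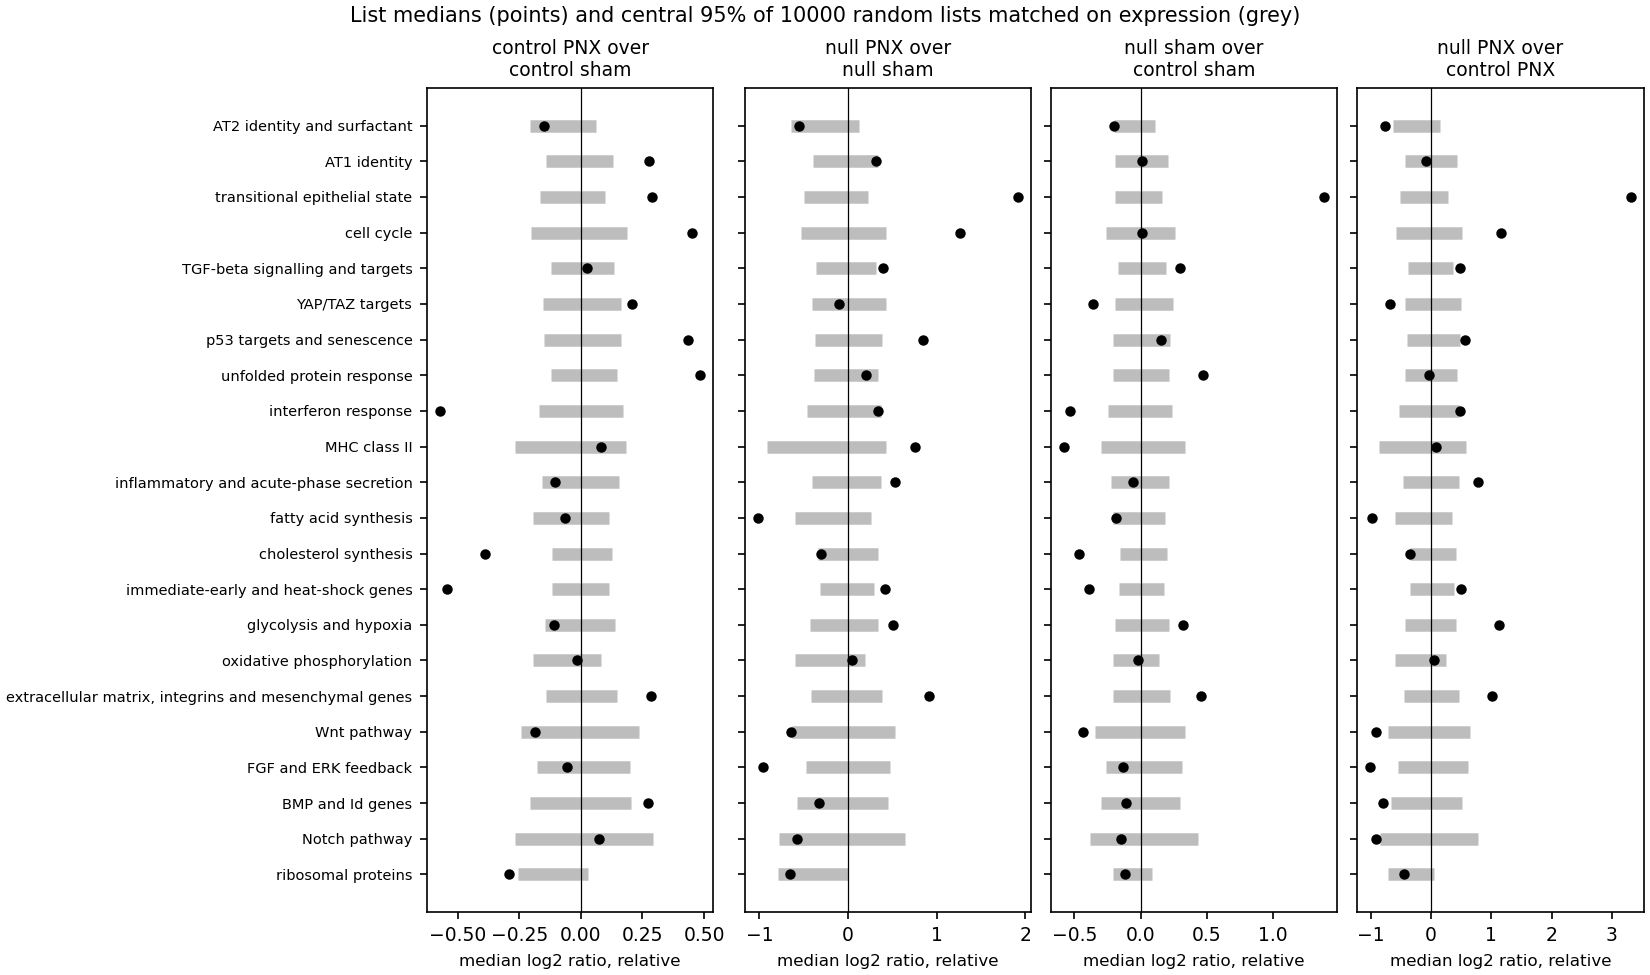
Median log2 ratio of each gene list relative to all genes (horizontal axis, points) in the 4 comparisons of libraries (panels), with grey bars for the central 95% of 10000 random lists matched on expression. The transitional list lies at 3.31 in null PNX over control PNX and at 0.29 in control PNX over control sham.

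The ratio of ratios divides the PNX-to-sham ratio of the null libraries by that of the control libraries, so it gives a direction and not which genotype differed more. It was above 1 at the median for transitional, interferon, inflammatory and cell cycle genes and below 1 for fatty acid and FGF genes. Interferon genes had PNX medians on opposite sides, -0.57 in control and 0.34 in null, while fatty acid genes had -0.07 in control and -1.02 in null. The interferon median of null turned to -0.04 with all cells summed. Null sham over control sham, without PNX, was also low for interferon genes, at -0.53. A difference of the control sham library is thus not ruled out for the control value and the ratio of ratios of these genes. Of 22 transitional genes 19 had a larger ratio in null and 0 a smaller one (median log2 1.72, percentile 100), including Plaur at 36.1, Sprr1a at 29.0 and Clu at 14.2. Interferon genes had a larger ratio in 10 of 13 cases (1.15, percentile 100), with Isg15 at 9.86, and 0 a smaller one. Inflammatory genes had a larger ratio in 8 of 14 cases (1.04), with Il1b at 5.19 and Chil1 at 3.48, and cell cycle genes in 8 of 10 (0.88, from 0.65 to 2.21 over the alternatives), with Birc5 at 33.1. In the same alveolar cells 3 of 5 macrophage markers (1.1985) and 3 of 4 club markers (1.75) also had a larger ratio, so RNA of those cells is not ruled out for the inflammatory genes. The club gene Scgb1a1 was lower after PNX in both genotypes, from 4967 to 1526 CPM in control and from 4841 to 1482 in null. Immediate-early and heat-shock genes had a larger ratio in 14 of 24 cases and a smaller one in 5 (0.85, percentile 100), with Atf3 at 20.7 and Hsph1 at 0.0940. MHC class II genes had a larger ratio in 5 of 7 cases (0.81), with H2-Eb1 at 18.3 and Cd74 at 1.87. The H2-Eb1 value rests on the control sham library, with 419 CPM against 30.8, 17.4 and 23.5 in control PNX, null sham and null PNX. Smaller ratios in null were found for 10 of 16 fatty acid genes (-0.88), with Scd1 at 0.299, for 10 of 24 AT2 identity genes (-0.42, percentile 8.42) and for 6 of 17 unfolded protein response genes (-0.43), with Herpud1 at 0.261. Null sham over control sham, without PNX, was -0.39 for immediate-early and heat-shock genes and 0.47 for unfolded protein response genes. A difference of the control sham library is thus not ruled out for these lists either.

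Among the genes named in advance the ratio of ratios was highest for Cyr61, at a log2 of 5.14 (4.65–5.64), then Ctgf at 3.87 (2.58–5.16) and Mki67 at 3.22 (2.0986–4.35). It was 1.36 for Hopx, 1.01 for Ager, 0.90 for Krt8, 0.68 for Tgfb1, 0.35 for Cdc42 (0.25–0.46) and -0.09 for Sftpc. The list medians were 0.63 for glycolysis and hypoxia, 0.44 for TGF-β, 0.34 for matrix and integrins, 0.26 for p53, 0.08 for AT1 identity, 0.03 for cholesterol, 0.02 for oxidative phosphorylation, -0.14 for YAP/TAZ (1.22 with only genes of at least 50 CPM), -0.37 for ribosomal proteins (percentile 32.5), -0.41 for BMP (percentile 9.93), -0.62 for Wnt, -0.71 for FGF and -0.77 for Notch. Across 2233 genes of at least 50 CPM the PNX log2 ratios of control and null had a Pearson r of 0.212 and a Spearman correlation of 0.196, and 63.1% had the same sign. The r was 0.034 for genes of at least 10 CPM and 0.363 for those of at least 200 CPM. Genes are not independent replicates, so these values describe the libraries only.

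Shares of alveolar cells with a UMI of a gene were compared after thinning every cell to 2500 UMIs, which left out 154 control sham, 128 control PNX, 205 null sham and 0 null PNX cells. The transitional genes Krt8, Clu and Krt19 were seen in most null PNX cells. Krt8 was seen in 26.5% of control sham, 29.5% of control PNX, 70.045% of null sham and 93.0% of null PNX cells (40.6%, 48.0%, 84.5% and 99.2% unthinned). Lymphocytes thinned alike gave 0%, 0%, 14.3% and 36.8%, from median depths of 2969, 2868, 2884.5 and 3394 UMIs against 4822, 4879, 5198 and 10771 in alveolar cells. These lymphocytes were only 42, 30, 56 and 87 cells, so the 0 shares allow up to 8.41% in control sham and 11.6% in control PNX. Clu was seen in 13.1%, 16.3%, 29.3% and 92.0% of cells in that order of libraries (22.5%, 27.7%, 45.2% and 99.2% unthinned), and in 55.2% of null PNX lymphocytes. Krt19 was seen in 7.96%, 12.4%, 38.3% and 74.7% (16.1%, 20.5%, 55.1% and 95.2% unthinned), and in 26.4% of null PNX lymphocytes.

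Cldn4 was seen in 0 of 1532 control sham cells, which allows up to 0.2405%, in 0.109% of control PNX, 1.40% of null sham and 31.7% of null PNX cells (0%, 0.203%, 2.69% and 53.2% unthinned). Null PNX lymphocytes had it in 4.60%. Itgb6 was seen in 0.849%, 1.79%, 1.19% and 12.9% of alveolar cells from control sham to null PNX (1.84%, 2.69%, 2.69% and 29.5% unthinned, with 1.15% of null PNX lymphocytes), Cyr61 in 1.57%, 1.79%, 1.15% and 18.9% (3.02%, 3.76%, 2.57% and 33.0% unthinned, 8.05%) and Sprr1a in 0.261%, 0.543%, 0.246% and 7.71% (0.356%, 0.660%, 0.341% and 17.4% unthinned, 0%). Ager was seen in 88.9%, 90.3%, 61.7% and 76.1% (95.2%, 96.2%, 78.6% and 93.0% unthinned), above the 23.8%, 16.7%, 10.7% and 23.0% of lymphocytes. Hopx, at 7.11%, 8.26%, 2.83% and 5.52%, was below the lymphocyte share in 3 of the libraries, at 19.0%, 6.67%, 16.1% and 19.5% in lymphocytes. Lymphocytes include NK cells that express Hopx, so they give no clean background for it and its shares are not read further. Mki67 was seen in 2.19% of null PNX cells (7.82% unthinned) and in 0.653%, 0.543% and 0.328% of the others. Lymphocytes gave 2.38%, 0%, 1.79% and 0% from control sham to null PNX, the 2.38% and 1.79% each from 1 cell.

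**Figure D3:**
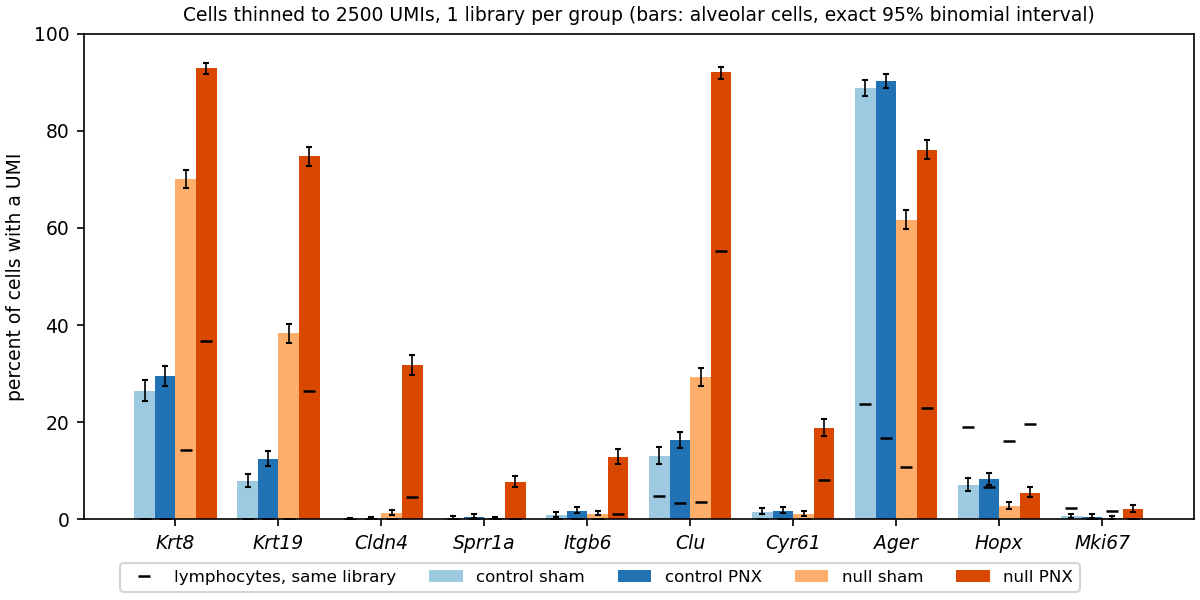
Percent of alveolar cells (vertical axis) with at least 1 UMI of each gene after thinning to 2500 UMIs, for the 4 libraries; bars are exact 95% binomial intervals and dashes are lymphocytes of the same library. Cldn4 was seen in 31.7% of null PNX cells and 1.40% of null sham cells.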

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

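The comparison at 1 minimum of 2669 UMIs per cell for every library was chosen only after the results were seen, because the lowest UMI count of a cell differed between libraries. Nothing was predicted for immediate-early and heat-shock genes, which were picked out because their median had opposite signs after surgery in the control and the null libraries. The median log2 ratio relative to all genes was -0.54 (95% interval -0.88 to 0.42) in control PNX over control sham and 0.42 (0.05–0.72) in null PNX over null sham, so the interval of the control median includes 0. The list was split in control PNX, with 11 of 24 genes lower and 5 higher. Null sham over control sham, without PNX, had a median of -0.39, so a difference of the control sham library is not ruled out. Atf3 was 2.92-fold lower in control PNX and 7.13-fold higher in null PNX, each against its own sham, but Hsph1 was 9.66-fold higher in control PNX. The difference was not tested, since each group is 1 library.

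Cells of other types in the GFP+ sort were picked out because no comparison of the report covers them and their share was above that of control sham with all cells held to the same minimum of UMIs. T/NK-like cells made up 3.36% of null PNX cells (95% interval 2.66–4.18) against 1.78% of control sham cells. An unnamed cluster with the T cell markers Cd3e, Cd3d and Cd3g had the reverse order over all cells, 4.36% of control sham (90 cells) against 1.57% of null PNX (36 cells), so T cells as a whole are given no order. Macrophage-like cells made up 3.62% (2.89–4.46) of null PNX cells against 0.888%, and neutrophil-like cells 0.915% (0.567–1.40) against 0.0592%. The neutrophil-like order depends on the minimum, which is that of null PNX itself. With all cells it was the reverse, 2.42% (50 cells) in control sham against 0.915%, and the minimum left 1 of the 50. The control sham and null PNX neutrophil-like cells were in different clusters. Clustered without listed genes, 0 null PNX cells had the neutrophil-like name, but an unnamed cluster led by Fcnb, Camp and Ngp held 22 of them. Mesothelial-like cells made up 0.828% (0.499–1.29) of null PNX cells, with 0 in control sham, and fibroblast-like cells 1.61% (1.18–2.15) of null sham cells against 0.651%. None of these differences was tested between animals, and how strictly each sort excluded GFP-negative cells is not given in the sources used here.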

How the results depend on the processing

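Of 1650 list medians under alternatives 1636 stayed within the interval of the main value, 12 moved outside it and 2 turned sign from an interval that excluded 0. The sign was the same for 1592. Of 1950 gene ratios 1645 stayed, 289 moved and 16 turned sign from such an interval, and 1924 had the same sign. Most list medians whose sign turned were near 0. Of 376 class shares 307 stayed and 69 moved, and of 68 thinned shares 15 stayed and 53 moved. The interferon median of null PNX over null sham turned from 0.34 to -0.042 with all cells summed, and that of null PNX over control PNX from 0.47 to -0.0412 at 50 CPM or more. The YAP/TAZ median turned from -0.10 to 2.32 in null PNX over null sham, from -0.67 to 3.97 in null PNX over control PNX and from -0.14 to 1.22 in the ratio of ratios at 50 CPM or more. The matrix and integrin median of control PNX over control sham turned from 0.29 to -0.09 with no filter. The transitional median of control PNX over control sham moved from 0.29 to 0.0396 in AT2-like cells alone. With all cells summed, the log2 ratios of control PNX over control sham were -0.53 for Chil3 (2.90 in the alveolar cells), -0.24 for S100a9 (2.22) and 0.00048 for Sftpc (-0.07). In AT2-like cells alone they were -0.68 for S100a8 (3.29), -1.19 for Chil3 and -1.46 for S100a9, while null PNX over null sham had 0.14 for Sftpc (-0.17), and null PNX over control PNX had 0.40 for S100a8 (-3.51). Clustered without listed genes, control PNX over control sham had -0.64 for S100a8, -1.30 for Chil3 and -1.47 for S100a9, and null PNX over control PNX had 0.41 for S100a8. Without the highest cell of each gene these were -0.63, -1.26, -1.46 and 0.40. The proliferating-like share of null PNX cells moved from 5.36% to 3.44% at resolution 0.4 and to 3.89% with no cell filter, and the class was not found when clustered without listed genes. The transitional-like share moved from 23.6% to 46.8% at resolution 1.5, 53.3% with the stricter cell filter, 46.844% with called doublets kept and 9.46% when clustered without listed genes. Pearson r between the PNX ratios of control and null moved from 0.212 to 0.034 at 10 CPM or more, 0.363 at 200 CPM or more and 0.133 in AT2-like cells alone, and the Spearman correlation from 0.196 to 0.0726, 0.422 and 0.0909. The cause was not tested for any of these. Clustering without listed genes, leaving out the highest cell, leaving out high doublet scores and the common minimum of UMIs were added after the data were seen. Other scalings cannot move list medians taken relative to all genes, and CPM filters cannot move the ratio of a gene. No paired analysis was possible because each group is 1 library and the labels pair none of them.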

Other observations

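Of the tests given here, those of other-cell RNA, of the shared direction of clock genes, with the reference of all other genes, and both of the genes set apart in control sham were chosen only after the result was seen. Circadian clock genes, which no list covered, differed between the 4 libraries. Dbp, a clock output factor that peaks once a day, had 37.7 CPM in control sham, 69.7 in control PNX, 209 in null sham and 12.3 in null PNX. Nr1d1 had 14.4, 114, 69.9 and 22.5 CPM in that order, Per3 29.3, 31.7, 64.8 and 9.67, and Arntl, which oscillates against them, 17.4, 5.14, 0.740 and 9.72. Dbp differed in the same way outside the alveolar cells between the libraries with the highest and lowest level, with 124 CPM in null sham and 21.4 in null PNX.

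Genes of other lung cell types were also compared within the alveolar cells. Macrophage markers had a median log2 ratio of -1.18 in control PNX over control sham and 1.10 in null PNX over control PNX. Club cell markers had 1.503 in null PNX over null sham and -1.42 in null sham over control sham. Their member Scgb1a1 was lower in the alveolar cells of null PNX than of null sham, at 1482 against 4841 CPM. Neutrophil markers had 2.08 in control PNX over control sham and -3.07 in null PNX over control PNX. Of these markers S100a8 and S100a9 had 93.5% and 92.2% of their control PNX UMIs in 1 cell each. Scgb1a1, the club cell gene, had 915, 346, 1301 and 748 CPM in lymphocytes from control sham to null PNX. Xist reached at most 1.09 CPM and Ddx3y at least 28.2 CPM in every library, the pattern of male cells.

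The clock differences may come from the time of day at collection, which all cell types of a lung would share. Among 33 pairs of a clock gene and a comparison at least 2-fold apart in alveolar cells, 32 (97.0%) had the same direction in the other cells, but so did 83.4% of 4094 such pairs of all other genes, so this leaves the time of day open. The pairs share genes and libraries and have no interval. Free RNA of alveolar cells was a poor explanation, because clock genes kept a level in other cells that was 4.05 times (3.50–6.45) what surfactant genes kept. The time of collection is not given in the sources used here, and the differences of Klf15, Dbp, Tef and Nr1d1 between libraries cannot be ascribed to surgery or genotype.

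Higher transitional genes in null PNX than in control PNX could come from depth, from other cells or from a shift of the whole library. In cells of 3000 to 7000 UMIs the median log2 ratio was 3.47 (2.1008–4.08) against 3.31 in all cells, so depth does not account for it. The same genes had a median log2 ratio of 1.03 (0.50–1.76) in alveolar over other cells of null PNX, which leaves a part of other-cell RNA open. In lymphocytes, where 17 of the 22 genes had 10 or more UMIs, the ratio was 2.18 (0.79–3.67), 1.13 below that of alveolar cells, so free RNA or a shift of the whole library may carry part of the difference.

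With 0.5 counts added, control sham stood apart from all 3 other libraries by 4-fold or more in 8 genes, higher for Dynlrb2, Gm26870, Gm10116, Ifi27l2a and H2-Eb1 and lower for Lamb3, Cldn4 and Fxyd4, although Cldn4 rests on 0 UMIs and is only at least 1.37-fold apart from control PNX at the floor of 3 counts. A strain or haplotype difference between animals might show in every cell type, and 3 of the 8 genes, or 37.5% (8.52–75.5), differed by 2-fold or more the same way in other cells, which leaves it open. These were Lamb3, Gm10116 and H2-Eb1, and H2-Eb1 lies in the MHC region at chromosome 17 34305867–34316674. Free RNA of alveolar cells in other droplets was a poor explanation. For the 5 higher genes the ratio between other and alveolar cells was 25.2 times (range over the genes 6.16–34.6) that of surfactant genes. This test cannot exclude the reverse, RNA of other cells in alveolar droplets. In control sham H2-Eb1 had 1740 CPM in other cells against 419 in alveolar cells, Ifi27l2a 949 against 286 and Dynlrb2 168 against 55.4. Of the higher genes only Gm26870 was lower in other cells, at 26.2 against 35.3 CPM. The 4-fold measure gave 9 genes for control PNX, 6 for null sham and 94 for null PNX.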
